A study of Homo sapiens with 27 samples.

How the data were processed

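RNA from right ventricular myocardium was measured on Affymetrix human exon arrays in 27 samples, with 1 array per sample. The samples were 16 infants with tetralogy of Fallot (TOF), 8 normally developing infants (control) and 3 fetal hearts. The deposited values are intensities on a linear scale, 1 per transcript cluster (a group of exon probes assigned to a transcribed region). Per the submitters' processing notes the authors used RMA in Partek with the genome build hg18. Versions, settings, the probe set level and any batch removal are not given in the sources used here. The log2 of each deposited intensity was computed here, with no added constant and no filter, and all tests ran on that scale. The number of arrays limits the precision.

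The table held 22011 transcript clusters. In the platform annotation 14432 of them had 1 gene symbol, 2408 had several and 5171 had none listed. Symbols were updated through the gene ID in a RefSeq gene table of the assembly GRCh38.p14, where 14404 matched, and no coordinates were taken from it because the builds differ. Clusters with several symbols were never named. For gene-level results the cluster with the highest mean over all arrays stood for its gene, which gave 14223 genes, and 197 genes had more than 1 cluster. Genes of the Y chromosome, XIST and TSIX (9 clusters) were left out of gene tables.

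Array file names in the labels carry a run code. Run 1 held 5 control and 12 TOF arrays, run 2 held 3 control and 4 TOF arrays, and run 3 held the 3 fetal arrays. TOF was compared with control in the 24 infant arrays with the run as a term. Fetal heart was compared with control and with TOF in a fit of all 27 arrays without a run term, since the fetal group and run 3 are the same arrays. Fits used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment over all clusters and a threshold of 0.05, two-sided. Array measures were compared with two-sided exact permutation tests, adjusted over 9 tests.

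Of 42 gene lists fixed before the data were examined, 41 had at least 5 measured genes and were tested with limma's camera at a preset inter-gene correlation of 0.01. Each list was also tested with an estimated correlation and with fry. The genes named were chosen by a rule fixed at the same time. For each comparison it took the 10 largest rises and 10 largest falls among genes past the threshold whose higher group lay above the median log2 level of all clusters (7.03), up to 4 members of each list with the smallest p, and a fixed set of cardiac and globin genes. The genes printed are a selection of those that met this rule, made after their values were seen. Some named genes belong to families of near-identical sequence (histones, HLA genes, TAS2R taste receptors), where probes can bind transcripts of relatives, so their single-gene values are uncertain.

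Correlation and covariance of the TOF and fetal shifts from control were set beside 100 simulations of unchanged groups against the same controls and beside all 70 splits of the controls into 4 and 4 arrays. The overlap of calls was set beside the same simulations and splits, each refitted with limma. Alternatives covered array scaling, the run, array weights, a filter on low levels, other tests and leaving out single arrays. The scripts were tested on simulated data with 22011 clusters of which 200 were changed. For TOF versus control, 52 of 100 clusters changed by 0.5 log2 and 90 of 100 changed by 1 log2 were recovered. For fetal versus control the numbers were 14 and 69 of 100, and for TOF versus fetal 18 and 70 of 100. No pair of arrays held identical values. Nothing in the labels says how the infants' samples relate to each other beyond their groups.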

Results

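Expression was measured in right ventricular myocardium of 16 infants with TOF, a heart malformation with an obstructed right ventricular outflow, of 8 normally developing infants and of 3 fetal hearts. Controls had a brighter dim end than TOF arrays, with a lower quartile of intensity of 62.6 ± 5.13 (SD, n = 8) against 46.9 ± 5.09 (SD, n = 16). On the log2 scale, where the test ran, TOF minus control was -0.42 (exact permutation p = 5.44e-06, adjusted p = 2.45e-05). Fetal arrays lay between them at 54.5 ± 4.36 (SD, n = 3). The first principal component held 42.3% of the variance and parted TOF from control arrays, and the second held 14.8% and set the fetal arrays apart. The first component also tended to follow the lower quartile within groups. Control replicates 7 and 1, with the highest and lowest lower quartile of the controls, lay at -98.4 and -31.8 on it. TOF replicates 13 and 4, with the highest and lowest of the TOF arrays, lay at -7.70 and 70.0. Arrays of a group correlated at a mean r of 0.959 across clusters in controls, 0.976 in TOF and 0.970 in fetal heart.

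**Figure D1:**
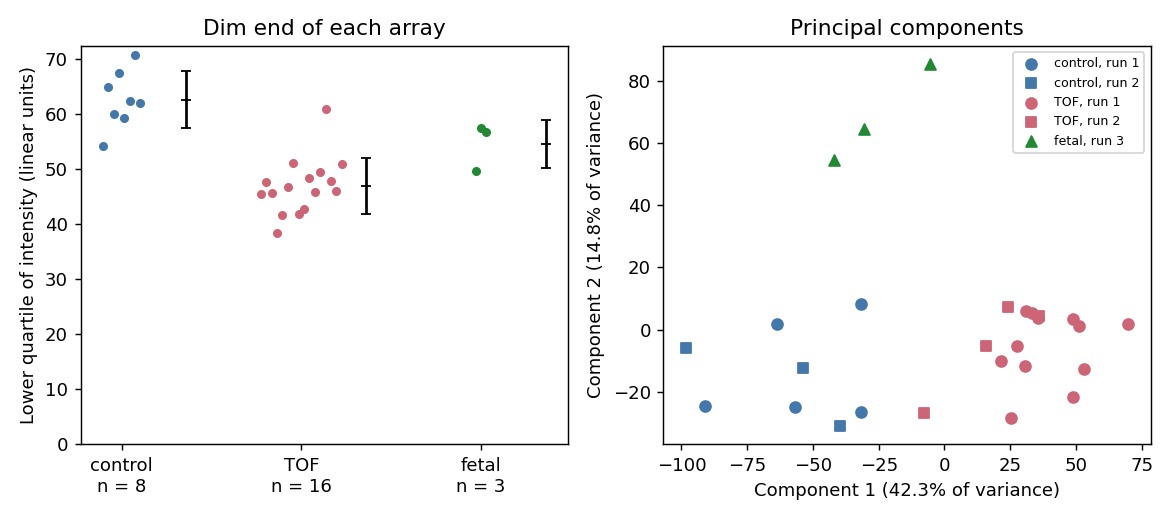
Left, lower quartile of intensity (linear units) of each array by group, with mean and SD as bars beside the points; right, the arrays on principal components 1 and 2, with the array run as the marker. The lower quartile averaged 62.6 in control, 46.9 in TOF and 54.5 in fetal arrays, and TOF replicate 13, at 60.9, lay within the control range of 54.2 to 70.7.

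The first comparison asked how TOF myocardium differs from that of normally developing infants. ACADM, which starts the oxidation of medium-chain fatty acids, rose by 2.15 ± 0.21 log2 (SE, 16 against 8 arrays), and PDK4, which holds pyruvate back from oxidation, rose by 2.42 ± 0.42. LDHA, a subunit of lactate dehydrogenase, rose by 1.64 ± 0.12. The transcription factor genes FOS at -1.69 ± 0.25, FOSB at -1.04 ± 0.16 and JUND at -0.68 ± 0.10 were lower.

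Among the largest rises were TPMT (7.99-fold, SE 0.23 log2), SPRYD4 (2.67 ± 0.13), DOK5 (2.57 ± 0.17), the proteasome subunit PSMA2 (2.57 ± 0.14), SDHC of succinate dehydrogenase (2.39 ± 0.24), the selenium carrier SELENOP (2.38 ± 0.11) and lysozyme, LYZ (2.32 ± 0.27). Among the largest falls were SNAP91 (-2.73 ± 0.37), beta globin, HBB (-2.21 ± 0.51), PPP1R1A (-2.02 ± 0.14), SNRNP70 of the U1 particle (-1.75 ± 0.18) and LUC7L3 (-1.71 ± 0.13). SPRYD4 had a limma adjusted p of 3.39e-13 and HBB one of 0.000577.

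Against control 3137 of all 14223 genes rose and 7606 fell, the background for the list counts below. Of 33 measured fatty acid oxidation genes 19 rose and 4 fell, with ACAA2 at 1.39 ± 0.14 and ETFDH at 1.26 ± 0.13. Of 56 oxidative phosphorylation genes 26 rose and 14 fell, with NDUFA5 at 1.68 ± 0.16 and NDUFC2 at 1.44 ± 0.11 on one side and NDUFS6 at -1.15 ± 0.10 on the other. After median centring 33 oxidative phosphorylation genes rose and 6 fell, and after quantile normalization 26 rose and 18 fell. Of 24 glycolysis and lactate genes 13 rose and 3 fell, with PGK1 at 0.99 ± 0.07 and PFKM at 0.98 ± 0.13. Of 20 sarcomere genes 12 rose and 1 fell, with XIRP2 at 1.64 ± 0.22 and ACTC1 at 0.50 ± 0.06, while TPM1 was lower by -0.36 ± 0.06. Of 29 heat shock and folding genes 16 rose and 6 fell, with HSPB1 at 1.02 ± 0.12 and HSPD1 at -1.11 ± 0.14. Antigen presentation genes included 8 that rose and 3 that fell of 17, with HLA-DPB1 at 2.27 ± 0.24 and HLA-DRA at 1.63 ± 0.18. Interferon response genes included 4 that rose and 2 that fell of 33, with EIF2AK2 at 1.15 ± 0.25, and 15 and 1 after median centring or 8 and 2 after quantile normalization. As deposited, smaller shares of the interferon genes rose and fell than of all genes. Macrophage and monocyte markers included 5 that rose and 1 that fell of 15, with F13A1 at 0.84 ± 0.17 and CSF1R at 0.50 ± 0.09, and 8 and 0 after median centring or 10 and 0 after quantile normalization. Of 32 immediate early genes 0 rose and 25 fell, and of 19 Hedgehog pathway genes 1 rose (KIF3A, 0.72 ± 0.12) and 15 fell, with SMO at -0.82 ± 0.08. Of 45 splicing regulators 8 rose and 28 fell, with HNRNPH1 at -1.03 ± 0.10 and HNRNPM at -0.96 ± 0.11, a list that camera did not call (adjusted p = 0.395; adjusted p = 0.809 with an estimated correlation) and in which 10 rose and 17 fell after median centring. Adjusted over the list alone, 1 and 2 interferon response genes, 7 and 2 antigen presentation genes, 5 and 0 macrophage markers, 18 and 6 heat shock genes, 0 and 26 immediate early genes and 1 and 16 Hedgehog genes rose and fell. The counts adjusted over the list alone were the same as over all genes for fatty acid oxidation, oxidative phosphorylation, glycolysis, sarcomere and splicing regulator genes.

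Camera called 10 of the 41 lists, 8 upward and 2 downward, those of the paragraph above apart from the splicing regulators. After quantile normalization 5 lists were called, since the calls of oxidative phosphorylation (adjusted p = 0.278), glycolysis and antigen presentation (0.0697 each), heat shock (0.0811), interferon response (0.0779) and macrophage genes (0.0604) ended and the splicing regulators were called downward (adjusted p = 0.00458). Median centring ended the call of interferon response genes (adjusted p = 0.0894). A filter that left out the lowest 33.3% by level ended the calls of antigen presentation (adjusted p = 0.124), interferon response and macrophage genes (0.167 each). The array lower quartile as a covariate, chosen after seeing the data, ended those of sarcomere, Hedgehog, oxidative phosphorylation, glycolysis, immediate early, heat shock and interferon genes (adjusted p from 0.0896 to 0.861), and with it splicing regulators and snRNP protein genes were called downward (adjusted p of 9.32e-09 and 0.0215). None was called with an estimated correlation (adjusted p = 0.784 with an estimated correlation for each of the 10), while at an unadjusted p under 0.05 camera then called 0 and fry called 25 after adjustment. Random splits of the 24 arrays called at least as many lists in 64 of 100 splits.

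Of the fixed cardiac genes, the natriuretic peptide NPPA was higher by 1.69 ± 0.63 (limma adjusted p = 0.0194), skeletal actin ACTA1 by 1.42 ± 0.26 and TBX5 by 0.72 ± 0.17. NKX2-5 fell by 0.54 on the log2 scale. Values that did not pass were 0.18 ± 0.45 for NPPB, 0.09 ± 0.09 for GATA4, -0.17 ± 0.14 for JAG1 and -0.02 ± 0.11 for ATP2A2, and GATA4 passed after median centring (0.30). The call of NPPA ended within each run alone and that of 29 named genes ended in run 2 alone. The splicing regulator RBFOX2 was lower by -0.27 ± 0.07, a call that ended after median centring (-0.06), while the value was -0.43 after quantile normalization.

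In all, 16111 of 22011 clusters (73.2%) passed in limma, 4297 higher and 11814 lower in TOF. The median difference of all clusters was -0.32, and after median centring of the arrays it was -0.11. The split was then 6025 higher and 7795 lower, and after quantile normalization 5408 and 6612. Relative to the array median, the list medians were 0.65 for fatty acid oxidation, 0.53 for sarcomere, -0.38 for immediate early and -0.08 for splicing regulator genes. After quantile normalization they were 0.41, 0.41, -0.50 and -0.38 in that order. With the lower quartile of each array as a covariate, chosen after seeing the data, 2693 clusters passed and the calls of 18 of the 69 named genes that had passed ended, among them HBB, XIRP2, HSPD1, FOS, FOSB, JUND, KIF3A, NPPA, ACTA1, TBX5 and EIF2AK2. The 7 arrays of run 2 alone gave 1495 clusters.

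**Figure D2:**
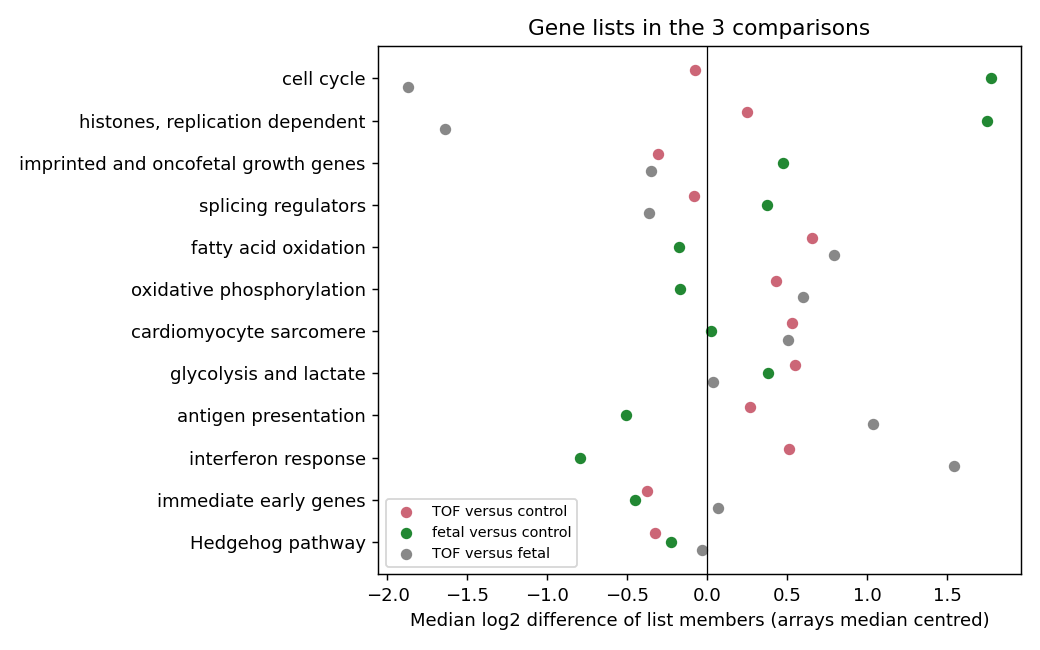
Median log2 difference over the members of 12 gene lists (horizontal axis, arrays median centred) in the 3 comparisons, 1 point per list and comparison. Cell cycle genes had medians of 1.78 in fetal versus control and -1.87 in TOF versus fetal, against -0.08 in TOF versus control, where the median was 0.07 after quantile normalization.

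The second comparison asked how fetal heart differs from that of normally developing infants. Of all 14223 genes 2214 rose and 3882 fell, the background for the list counts of this comparison. Genes of cell division were higher in fetal heart. TOP2A, which untangles replicated DNA, rose by 4.69 ± 0.43 log2 (SE, 3 against 8 arrays), ANLN by 4.39 ± 0.50, the mitotic motor KIF11 by 3.90 ± 0.22 and CENPF by 3.83 ± 0.31. Of 57 cell cycle genes 48 rose and 0 fell, and of 41 replication-dependent histone genes 33 rose and 0 fell, with H3C3 at 5.11 ± 0.51 and H1-1 at 3.59 ± 0.24. Of 20 sarcomere genes 1 rose and 5 fell, among them MYOM2 of the M band at -4.18 ± 0.20 and TCAP of the Z disc at -2.73 ± 0.19, a list that camera did not call (adjusted p = 0.465; adjusted p = 0.872 with an estimated correlation) and whose median was -0.07 as deposited, 0.02 after median centring and -0.19 after quantile normalization. MYOM3, outside that list, was lower by -2.68 ± 0.25.

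NPPA rose by 5.07 ± 0.97 and SULT1E1, an estrogen sulfotransferase, by 4.89 ± 0.20. PEBP4 (-3.04 ± 0.50), STEAP4 (-2.76 ± 0.26) and the phosphodiesterase PDE3A (-2.69 ± 0.31) were among the largest falls. Of 19 imprinted and oncofetal growth genes 8 rose and 2 fell, with IGF2BP1 at 2.11 ± 0.18, PEG10 at 1.95 ± 0.27 and NNAT at 1.73 ± 0.21. Of 45 splicing regulators 21 rose and 3 fell, with NONO at 1.38 ± 0.18, KHDRBS1 at 0.99 ± 0.15, PTBP1 at 0.86 ± 0.13 and RBFOX2 at 0.48 ± 0.11. Of 24 glycolysis and lactate genes 9 rose and 2 fell, with PDK1 at 2.34 ± 0.20 and LDHA at 2.16 ± 0.18. HIF1A rose by 1.19 ± 0.16 and EPAS1 was lower by -1.18 ± 0.15. Of 42 BMP and TGF-beta pathway genes 15 rose and 9 fell, with BMPR2 at 1.72 ± 0.21 and SMAD1 at 1.02 ± 0.13.

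Of 17 antigen presentation genes 0 rose and 11 fell, with CD74 at -1.71 ± 0.25 and HLA-E at -1.55 ± 0.15. Lymphocyte markers included 0 that rose and 9 that fell of 22, with CD3E at -2.11 ± 0.25. Of 33 interferon response genes 15 fell and 1 rose (XAF1, 1.21 ± 0.24), with IFI44L at -3.29 ± 0.67 and IFITM1 at -2.39 ± 0.41. Of 32 immediate early genes 0 rose and 17 fell, with DUSP1 at -2.10 ± 0.34 and NR4A1 at -1.87 ± 0.39. Erythroid markers included 4 that rose and 1 that fell of 11, with the embryonic globin HBZ at 1.99 ± 0.36 and ALAS2 at 1.36 ± 0.23. Adjusted over the list alone, 48 cell cycle genes rose and 1 fell, 34 histone genes rose and 0 fell, 21 splicing regulators rose and 3 fell, 1 interferon gene rose and 17 fell, and 0 immediate early genes rose and 21 fell. Macrophage markers (0 and 1 of 15), acute inflammation genes (1 and 7 of 32) and neutrophil markers (1 and 5 of 15) were not called, with adjusted p of 0.317, 0.376 and 0.147.

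Camera called 15 lists, 10 upward and 5 downward. With an estimated correlation 2 of them held, cell cycle (adjusted p = 0.00827 with an estimated correlation) and histones (adjusted p = 0.00725 with an estimated correlation). Random splits gave as small a list p in 1 of 100 for cell cycle, the real grouping alone, and in 4 of 100 for histones. The imprinted list had an adjusted p = 0.052 with an estimated correlation and the splicing regulators an adjusted p = 0.265 with an estimated correlation. For glycolysis and BMP and TGF-beta genes the adjusted p = 0.452 with an estimated correlation, for antigen presentation, lymphocyte and erythroid genes the adjusted p = 0.53 with an estimated correlation, for immediate early genes the adjusted p = 0.636 with an estimated correlation and for interferon genes the adjusted p = 0.728 with an estimated correlation. Of the other called lists, snRNP protein genes (16 rose and 3 fell of 54) and Schwann cell and neuron markers (0 and 6 of 10) had an adjusted p = 0.452 with an estimated correlation. Heat shock genes (9 and 3 of 29) had an adjusted p = 0.53 with an estimated correlation and extracellular matrix genes (9 and 5 of 48) an adjusted p = 0.728 with an estimated correlation. Quantile normalization ended the calls of BMP and TGF-beta (adjusted p = 0.0672), heat shock (0.0645) and extracellular matrix genes (0.220). With the lowest 33.3% by level left out, the calls of BMP and TGF-beta (adjusted p = 0.0822), extracellular matrix (0.174) and erythroid genes (0.904) ended. Random splits called at least as many lists in 28 of 100 splits. In limma 8493 clusters passed, 3375 higher and 5118 lower, with a median difference of -0.17. Without fetal replicate 1 the count was 3837, and the fetal group and array run 3 cannot be told apart.

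**Figure D3:**
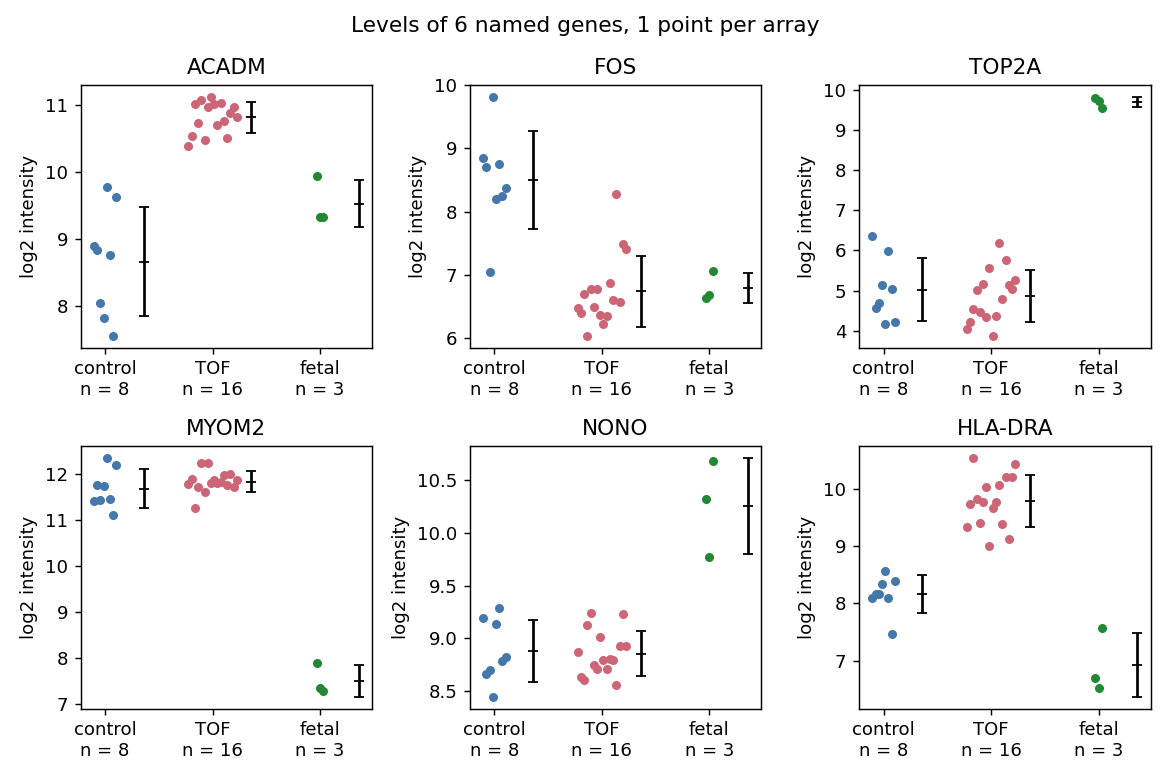
Log2 intensity of 6 named genes, 1 point per array by group, with mean and SD as bars beside the points. ACADM and HLA-DRA were higher in TOF than in control by 2.15 and 1.63, FOS was lower by -1.69, and TOP2A, MYOM2 and NONO set fetal heart apart from control by 4.69, -4.18 and 1.38.

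The comparison of TOF with fetal heart asked where diseased infant myocardium stands against fetal tissue. Of all 22011 clusters 2665 were higher and 4563 lower in TOF, the background for the list counts of this comparison. Dividing-cell genes were lower in TOF, with TOP2A at -4.85 ± 0.40 (SE, 16 against 3 arrays), CENPF at -4.25 ± 0.29 and MKI67 at -4.00 ± 0.27. Of 57 cell cycle genes 2 rose and 52 fell, and of 41 histone genes 1 rose and 36 fell. Of 20 sarcomere genes 7 rose, with MYOM2 at 4.33 ± 0.19, XIRP2 at 3.71 ± 0.36 and TCAP at 3.11 ± 0.17, 1 fell and 12 did not pass (adjusted p = 0.437 with an estimated correlation). After median centring 11 of them rose and 0 fell, and after quantile normalization 15 and 0.

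Of 33 fatty acid oxidation genes 21 rose and 1 fell, and of 56 oxidative phosphorylation genes 24 rose and 2 fell, with COX7A1 at 1.28 ± 0.19 and COX6A2 at 1.07 ± 0.18. ACSL1, which activates long-chain fatty acids, rose by 3.27 ± 0.29 and the fatty acid carrier CD36 by 1.65 ± 0.15. Of 17 antigen presentation genes 12 rose and 0 fell, with HLA-DRA at 2.85 ± 0.26 and CD74 at 2.43 ± 0.23, and of 33 interferon response genes 21 rose and 1 fell, with IFI44L at 4.23 ± 0.62. Of 45 splicing regulators 3 rose and 30 fell, with SRSF7 at -1.64 ± 0.19, NONO at -1.40 ± 0.17, SFPQ at -1.04 ± 0.12 and RBFOX2 at -0.76 ± 0.10. Of 19 imprinted and oncofetal growth genes 0 rose and 10 fell, with IGF2BP1 at -2.74 ± 0.16, PEG10 at -2.72 ± 0.25 and NNAT at -2.36 ± 0.19. Erythroid markers included 1 that rose and 6 that fell of 11, with AHSP at -2.52 ± 0.28. SULT1E1 (-5.44 ± 0.19), NPPA (-3.48 ± 0.90), the pacemaker channel HCN4 (-1.41 ± 0.17) and TBX20 (-1.14 ± 0.17) were lower, while the beta receptor ADRB1 (2.20 ± 0.21), ACTA1 (2.54 ± 0.43) and KCND3 (1.24 ± 0.15) were higher. Adjusted over the list alone, 2 cell cycle genes rose and 52 fell, 3 splicing regulators rose and 33 fell, 0 imprinted genes rose and 11 fell, and 25 interferon genes rose and 1 fell. Of 32 immediate early genes 2 rose and 2 fell, of 24 glycolysis and lactate genes 7 and 10, and of 29 heat shock genes 5 and 4. Camera called none of these lists here (adjusted p of 0.949, 0.937 and 0.748). Against the same 8 controls, camera had called each in the same direction in TOF and in fetal heart. The lack of a call against 3 fetal arrays does not show equal levels, and single glycolysis genes differed both ways.

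Camera called 16 lists, 8 in each direction. Cell cycle, histones and imprinted genes held (adjusted p = 0.00912 with an estimated correlation for each). For each of these 3 lists 1 of 100 random splits, the real grouping alone, gave as small a list p. The splicing regulators had an adjusted p = 0.0707 with an estimated correlation, fatty acid oxidation and antigen presentation an adjusted p = 0.233 with an estimated correlation, erythroid genes an adjusted p = 0.437 with an estimated correlation, and oxidative phosphorylation and interferon genes an adjusted p = 0.513 with an estimated correlation. Calcium handling genes (13 rose and 3 fell of 32) and ribosomal protein genes (0 and 8 of 25) had an adjusted p = 0.437 with an estimated correlation, macrophage markers (9 and 0 of 15) an adjusted p = 0.513 with an estimated correlation and epicardial markers (0 and 5 of 12) an adjusted p = 0.553 with an estimated correlation. Lymphocyte markers (4 and 0 of 22) and extracellular matrix genes (2 and 17 of 48) had an adjusted p = 0.666 with an estimated correlation. After median centring and after quantile normalization the lymphocyte counts were 8 and 0 and 12 and 0, those of matrix genes 2 and 11 and 2 and 12, and those of ribosomal protein genes 1 and 4 and 1 and 5. Quantile normalization ended the call of calcium handling genes (adjusted p = 0.0812). The calls of erythroid (adjusted p = 0.219) and lymphocyte genes (0.214) ended with the lowest 33.3% by level left out. Random splits called at least as many lists in 14 of 100 splits. In limma 7228 clusters passed, 2665 higher and 4563 lower in TOF, with a median difference of -0.11. After median centring the median was 0.03 and the split 3809 and 3188, and after quantile normalization 4072 and 3388. TOF infants of run 2 alone gave 4314 clusters and array quality weights gave 12994.

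Across 14223 genes, which are not independent replicates, the shifts of TOF and fetal heart from control correlated at r = 0.465 with a covariance of 0.150. Unchanged groups simulated against the same controls gave a mean r of 0.536 and a covariance of 0.0138. With the controls split between the comparisons, the mean r was 0.414 and the mean covariance 0.136. Genes higher in both comparisons numbered 1282 where independent lists would share 488.3, and genes lower in both numbered 3073 against 2076. Unchanged groups simulated against the same controls shared a mean of 2.95 genes higher in both (highest 113) and 6.99 lower in both (highest 375). With the controls split, a mean of 1021 genes were higher in both against 379.2 for independent lists, and 2009 lower in both against 1379. Genes higher in TOF and lower in fetal heart numbered 244 against 856.2 for independent lists, and 346 went the other way against 1184. The simulation leaves out the effects and the independent value the shared controls, so neither excess measures a shared effect.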

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

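The tests of scaling, of array run, of shared controls and of single lists against random splits in this part were chosen after their results were seen, and the other tests were fixed before. In the 8 control arrays, 10 of 144 measures had 1 array far from the rest, given as its gap to the nearest array over the group's range, where chance alone gives about 1 in 20. The ratios were 0.651 for SRSF7, 0.557 for NR4A1, 0.538 for FOSB and 0.528 for JUND (control replicate 4), 0.569 for GATA5 and 0.568 for HLA-DRA (control replicate 7), 0.600 for CSF1R (control replicate 1), 0.569 for ANKRD1 (control replicate 3), 0.531 for SNAP91 (control replicate 2) and 0.529 for DLGAP5 (control replicate 5).

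Chance is argued against for the counts of clusters, though 100 splits cannot show a share under 1 of 100. In each comparison only the real grouping, 1 of 100 splits, reached its count. The counts were 16111 for TOF versus control (highest other split 3360), 8493 for fetal versus control (highest other 5582) and 7228 for TOF versus fetal (highest other 732). For fetal versus control this is weaker, since the count was 3837 without fetal replicate 1. Chance cannot be excluded for the number of lists called at the preset correlation. As many lists were called in 64 of 100 splits for TOF versus control (10, highest other 21), 28 of 100 for fetal versus control (15, highest other 20) and 14 of 100 for TOF versus fetal (16, highest other 22). Chance is argued against for cell cycle genes in both comparisons with fetal heart and for histones and imprinted genes in TOF versus fetal, where the real grouping alone, 1 of 100 splits, gave as small a list p and the call held with an estimated correlation (highest adjusted p = 0.00912). In fetal versus control imprinted genes had 1 of 100 splits, with an adjusted p = 0.052 with an estimated correlation, and histones had 4 of 100, with a call that held with an estimated correlation (adjusted p = 0.00725). Adjusted over the 41 lists, the shares were 0.205 for cell cycle and imprinted genes and 0.547 for histones in fetal versus control. They were 0.137 for cell cycle, histones and imprinted genes in TOF versus fetal. No adjusted share passed 0.05, though 1 of 100 is the smallest share that 100 splits can give. The argument against chance for these lists therefore rests on unadjusted shares and on camera with an estimated correlation.

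Most clusters differed between TOF and control. Scaling of whole arrays alone is argued against, since 12020 clusters passed after quantile normalization, as is array run, since 15031 passed within run 1. Quantile normalization does not remove a bias that differs between clusters of the same level. With the array lower quartile as a covariate, which differs between the groups, 2693 clusters passed. A sample condition that also varies within groups, such as RNA or tissue handling, stays open: slopes on the array lower quartile within TOF correlated across genes with the control minus TOF difference at 0.494 (0.463 without TOF replicate 13), just under the 0.5 set beforehand as what that cause would give, while slopes within control correlated with it at 0.592, a value for which no bound was set. Controls and TOF tissue may also differ in how they were obtained, which the labels do not settle, and the disease itself remains untested against it.

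Of 45 splicing regulators 30 fell and 3 rose in TOF against fetal heart (adjusted p = 0.0707 with an estimated correlation). Chance cannot be excluded for this list, since 7 of 100 random splits gave as small a p. Scaling of whole arrays is argued against by a list median of -0.47 after quantile normalization. A sample condition that follows the array lower quartile is argued against by slopes on that quartile within TOF. They predict -0.145 of the observed median, the opposite direction, with a range of -0.260 to -0.0854 when 1 TOF array was left out. A condition that differs between fetal and infant tissue without following that quartile was not tested. Array run cannot be told apart from the fetal group, and age of the tissue and disease may each contribute, untested.

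TOF and fetal shifts from control went together. Shared control arrays alone are argued against by the mean covariance of 0.136 with split controls, over the simulated 95th percentile of 0.0316. A sample condition is a candidate explanation, since 0.253 of the covariance was left once slopes within groups were removed. A common biological state remains untested.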

How the results depend on the processing

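The covariate, the joint omission of 3 arrays and the split of the controls for the overlap were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers shared between groups. Clusters for TOF versus control numbered 1495 in run 2 alone (7 arrays) and 2693 with the array lower quartile as covariate, which differs between the groups, and 6954 with a fold of at least 1.5, which gave 5054 for fetal versus control and 4788 for TOF versus fetal. TOF versus fetal gave 4314 with infants of run 2 and 12994 with array weights; the cause was not tested. Lists called for TOF versus control numbered 5 after quantile normalization, 0 with an estimated correlation and 25 with fry; an estimated correlation left 2 for fetal versus control and 3 for TOF versus fetal, where fry called 27. The overlap of same-direction genes was 4355, 2140 at the stricter 0.01 and a mean of 3029.9 with split controls. Leaving out 1 array gave 15159 to 16434, 3837 (without fetal replicate 1) to 9439, and 5115 to 7882 clusters, 8 to 11, 12 to 17 and 13 to 16 lists, and correlations of 0.370 to 0.512. Without control replicates 4 and 7 and TOF replicate 13, which had the lowest correlations with their groups, the clusters were 15155, 8000 and 8630. Single omissions ended the list calls of macrophage markers in TOF versus control (0.0508, without TOF replicate 13), of Hedgehog genes (up to 0.0591, without control replicates 1 or 7 or TOF replicate 13), of BMP and TGF-beta genes in fetal versus control (up to 0.0624, without control replicates 5 or 8) and of erythroid markers there (up to 0.200, without control replicates 1, 3, 5, 6 or 8 or fetal replicate 3). The same held for matrix genes there (up to 0.120, without control replicates 2, 5 or 8 or fetal replicate 3), and in TOF versus fetal for lymphocyte (0.147, without fetal replicate 1), epicardial (up to 0.0944, without fetal replicates 1 or 2) and ribosomal genes (up to 0.0830, without fetal replicates 1 or 3).

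Genes that had not passed changed sign without passing. For TOF versus control these were NPPB (-0.15, run 1), GATA4 (-0.15, run 2, and -0.0635, quantile normalized), ATP2A2 (0.0121, run 2, with 0.186, centred, and 0.0388, quantile normalized) and JAG1 (0.0193, covariate, and 0.0431, centred). For TOF versus fetal they were GATA4 (0.0417, run 1, and 0.0409, centred), NPPB (0.39, run 2, and 0.0343, array weights) and TBX5 (-0.26, run 2). Leaving out 1 array also turned signs without a call. For TOF versus control these were ATP2A2 (up to 0.0156, without control replicates 2 or 8 or TOF replicates 11 or 13) and NPPB (down to -0.0433, without TOF replicates 11 or 13). For fetal versus control they were JAG1 (down to -0.0995, without control replicates 2, 5 or 8 or fetal replicate 3) and NPPB (-0.15, without fetal replicate 1), and for TOF versus fetal NPPB (0.26) and TBX5 (-0.13), both without fetal replicate 1. Clusters were also ranked by mean level into 10 groups of about equal size. The median TOF minus control difference was -0.51 in group 2, near the dim end, and 0.21 in group 10, the brightest. The oxidative phosphorylation list had a median of 0.22 as deposited, much like the brightest clusters. Bias between dim and bright clusters thus limits what low-level genes can show, and also small rises of bright genes.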

Other observations

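Of 48 measured extracellular matrix genes 4 rose and 22 fell against control. Of all 14223 genes 3137 rose and 7606 fell, so the matrix list fell no more often than genes at large. COL1A1 was lower at -1.12 ± 0.38 log2, a call that ended without control replicates 4 and 7 and TOF replicate 13. POSTN, a matrix protein of remodelling heart, rose by 1.99 ± 0.28. Epicardial and mesothelial markers included 0 that rose and 8 that fell of 12, neutrophil markers 0 and 12 of 15, and erythroid markers 1 and 9 of 11, with ALAS2 at -0.95 ± 0.13. Camera called none of these 4 lists, and the neutrophil median was -0.52 as deposited and -0.11 after quantile normalization, where 2 neutrophil markers rose and 5 fell. The calcium-binding protein CASQ2 rose by 1.28 ± 0.10, BMPR2 by 1.60 ± 0.13 and MEF2C by 0.61 ± 0.08.

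All 16 TOF arrays lay on the called side of the control mean for 60 of the 69 named genes that passed in TOF versus control. All 3 fetal arrays did so for 64 of 64 genes in fetal versus control. The compared groups did not overlap for 43 of the 69 and 58 of the 64 genes. These genes were counted because they passed in the same arrays, and most were picked for large changes or small p. Agreement among arrays was therefore largely built into the choice. Its extent over all passing genes was not tested.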
